A study of Rattus norvegicus with 44 samples.

How the data were processed

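Liver RNA of 44 male Wistar rats was measured on Agilent 4x44K rat arrays with 2 dyes, 1 rat per array and 4 arrays on each of 11 slides. Per the labels, each sample carried Cy5 and a pool of all livers carried Cy3. The design text counts 1 more control rat than there are samples, and says that rats were housed 3 to a cage, while the labels give neither cage nor slide. There were 8 controls and 6 rats in each of the 6 treated groups.

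The deposited value table of the authors holds log2 ratios of sample over reference for 43379 spots, normalised by the authors with R 2.3.1, centred on the 8 control columns (the largest absolute control mean was 0.0038) and rounded to 2 decimals. In it 4961 features were 0.00 in every column, and 9075 had 1 value in all control columns. Per the file headers, the 44 deposited scanner files came from Agilent Feature Extraction 10.5.1.1 with probe positions on rat build rn4. They hold median intensity values of each spot and its background in both channels (deposited in scanner units, not logged). They also hold Agilent's log10 ratio of red over green, which per the file headers was corrected for background and dye bias, and flags of 0 or 1 (deposited as another kind of value), such as well above background and saturated. Mean signals were missing in 43 files, so median signals were used.

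The planned source was the scanner files. Each column of the value table was compared with each scanner file over the 18818 features above background in both channels on all 44 arrays. All 44 columns had 1 best file, with r between 0.905 and 0.971 and no second file above 0.59, and the matches were mutual. The best file was recorded for the same sample in 1 case and for another sample in 43, of another group in 37. Cyp1a1 was over 5 log2 units above the control mean in 6 of 6 columns labelled TCDD and in 0 others, while 1 of the files recorded for TCDD and 5 recorded for other groups had it above the reference. The value table with its own labels was therefore used in place of the planned source. This switch was made after the data were examined. The files as recorded were kept for comparison. The files matched by profile served for signal over background and slides, and for further comparison.

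Probes were kept if Cy5 was well above background on at least 5 of the 44 arrays, whatever their group, and if the values were not constant. This filter replaced one by group, since the links of files to groups were in doubt. Of the 27335 probes that passed, the brightest of each gene was used, which left 23396 genes, 11344 of them with a gene symbol, and 3246 with over 1 kept probe. Among them, 114 had 1 value in all control columns. Of 41012 probes, 10835 were named through an accession of the reference table, 5195 through a symbol, 3478 through a synonym, 73 through a second accession and 5 through a description, and 21426 kept the name in the file alone. Coordinates are those of the probe in the files, on rn4.

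A linear model with 1 mean per group was fitted to each gene with limma 3.58.1 in R 4.3.3, with moderated variances (prior degrees of freedom 3.19, median SD 0.148). Tests were two-sided, with Benjamini-Hochberg adjustment over the genes of each comparison and a threshold of 0.05. Intervals are 95% intervals of the model. Where a group had a probe above background on no array, the fold was given as a bound from the signals of the matched files. The comparisons were each treated group with control, 2-ITX at 500 with 50 mg/kg/day, flutamide with Casodex, and 2-ITX at 500 mg/kg/day with TCDD and with flutamide. Shared changes were counted beside those of independent lists, of 100 simulated sets of unchanged groups against the same controls, and of the 70 splits of the controls into 2 sets of 4, each for 1 comparison. Python 3.11.15 with pandas 2.3.3, numpy 2.4.6 and matplotlib 3.10.9 read the files and drew the figures.

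The comparisons, the threshold, 27 gene lists and the rule for naming genes were set before the data were examined. The rule named, for each comparison with control and for flutamide against Casodex, the 8 largest increases and 8 largest decreases among passing genes with a symbol, the 8 AhR control genes (Ahrr, 1 of them, was not on the array), up to 4 members with the smallest adjusted p of each passing list, and a fixed set of liver genes (Cyp2c11, Cyp2c12, Cyp2b1, Cyp3a23-3a1, Cyp4a1, Cyp7a1, Hmgcr, Fasn, Ar, Igf1 and Ghr). From these the genes that carry the comparison were described. Lists were tested with camera of limma at a preset correlation of 0.01 between genes, adjusted over the lists of a comparison, and again with an estimated correlation. They need at least 3 measured genes, and were not tested for 2-ITX at 500 against 50 mg/kg/day or against flutamide. The lists cover AhR, NRF2 and glutathione, CAR and PXR, and PPARA targets; male-predominant and female-predominant genes; the growth hormone axis; cholesterol, fatty acid and bile acid genes; gluconeogenesis and glycolysis; acute phase and unfolded protein responses; cell cycle, p53, circadian clock and thyroid hormone genes; pericentral and periportal genes; heme and iron; ribosomal proteins; and markers of Kupffer cells and leukocytes, stellate cells, cholangiocytes, endothelium, blood and pancreatic acini. Some genes are in more than 1 list: Nqo1, Gsta2 and Gsta3 in the AhR and NRF2 lists, Cyp3a9 and Cyp2c7 in the CAR and PXR and the female-predominant lists, and Cyp3a2 and Cyp3a18 in the CAR and PXR and the male-predominant lists.

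The fit was tested on simulated data with independent normal noise, at the spread of each gene pooled over all groups. Spread that differs by group, correlation between genes and structure by sample number were not simulated. Of simulated 1.5-fold changes, 83.6% were found for 2-ITX at 500 mg/kg/day, 88.1% at 150, 89.6% at 50, 92.5% for TCDD, 85.1% for flutamide and 89.6% for Casodex, and of 2-fold changes 97% or more. The false calls were 3 in 189 for 2-ITX at 500 mg/kg/day, 17 in 207 at 150, 14 in 205 at 50, 8 in 202 for TCDD, 6 in 194 for flutamide, 15 in 208 for Casodex, 8 in 195 for 500 against 50, 16 in 209 for flutamide against Casodex, 8 in 200 for 2-ITX against TCDD and 6 in 194 against flutamide. In 4 of these single runs (150 and 50 mg/kg/day, Casodex, flutamide against Casodex) that is over the 0.05 of the threshold. The list test called 2 of 540 unchanged lists and 20 of 20 shifted ones for that comparison. The number of arrays limits the precision.

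Alternatives covered the source files, background and normalisation, the filter, the probes of a gene, the samples in the fit, blocks for replicate number and slide, array weights, the variance model, the threshold, the list test, the controls and each array left out in turn. The division of sample numbers 1 to 3 and 4 to 6 was chosen after the values were seen, and was fitted with limma as 1 mean per group and set of numbers.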

Results

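Liver mRNA was measured in 44 male Wistar rats on 2-colour Agilent arrays, 1 rat per array. The rats received 31 daily doses by gavage in corn oil, from postnatal day 23 to day 53. The 8 control rats received the oil alone. The other 6 groups held 6 rats each and received 2-ITX (2-isopropylthioxanthone, a photoinitiator of printing inks) at 50, 150 or 500 mg/kg/day, TCDD (dioxin) at 50 ng/kg/day, flutamide at 50 mg/kg/day or Casodex (bicalutamide) at 30 mg/kg/day. The design text names TCDD as a strong agonist of the aryl hydrocarbon receptor (AhR), a sensor that switches on genes for the breakdown of foreign compounds. It names flutamide as a blocker of the androgen receptor that also activates the AhR, and Casodex as a blocker of the androgen receptor. The piece of liver was the processus papillaris of the caudal lobe. Each liver was labelled with Cy5 and compared with a Cy3 pool of all livers, on 11 slides of 4 arrays. On all 44 arrays, 18818 features were above background in both channels, and 23396 genes were tested, of which 11344 had a gene symbol. The number of arrays limits the precision.

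Values are log2 ratios to the mean of the controls, and a change is the difference of 2 group means ± its standard error, with 6 treated rats against 8 controls. Positions are those of the probe on build rn4. The scanner files were recorded under other samples than their values in the authors' table for 43 of 44 samples, so the table and its labels were used. Within groups, samples numbered 1 to 3 and samples numbered 4 to 6 differed in 3017 genes over the 2-ITX and flutamide groups and in 264 over the control, TCDD and Casodex groups, and 140 genes differed in this between the 2 sets of groups. Values of both sets of numbers are given apart where they matter. The division was chosen after the values were seen, and the labels do not explain it. P-values within 1 set of numbers are therefore descriptive.

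TCDD against control shows the genes that AhR activation reaches. Cyp1a1 had already served to choose the value table, so its rise here is not a second check of the labels. The genes that rose most were the classic AhR targets. Cyp1a1, which oxidises polycyclic aromatic compounds, rose by 9.99 ± 0.22 (1010-fold, higher in 6 of 6 rats, adjusted p = 6.25e-32, chromosome 8, 61468133 to 61468192). Its control signal was well above background on 6 of 8 arrays. Cyp1b1, a related oxidase, was not well above background in any control and was at least 14.2-fold higher with TCDD (adjusted p = 1.75e-29, chromosome 6, 2546002 to 2546061). Cyp1a2, the main caffeine-oxidising enzyme of the liver, rose by 3.98 ± 0.45 (adjusted p = 8.86e-08, chromosome 8, 61439236 to 61439295), and the aldehyde dehydrogenase Aldh3a1 rose by 3.85 ± 0.66 (adjusted p = 0.000419, chromosome 10, 47374804 to 47374862). Slco1a4, an uptake carrier for bile salts and other anions, fell by 1.02 ± 0.18 (adjusted p = 0.000539), and the peptidase Mme fell by 1.16 ± 0.21 (adjusted p = 0.00116, not passed in 3 of 18 alternatives), each lower in 6 of 6 rats.

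In all, 150 genes passed the threshold with TCDD, 133 higher and 17 lower. Of the 7 AhR control genes on the array, 5 rose. The quinone reductase Nqo1 was higher in 6 of 6 rats without passing (1.47 ± 0.44, adjusted p = 0.157, passed in 3 of 19 alternatives), and Tiparp, a feedback inhibitor of the AhR, was at 0.09 ± 0.11 (adjusted p = 0.894). Of 11 measured genes of the AhR list, 6 rose and none fell over all genes (9 and 0 adjusted over the list alone; camera adjusted p = 1.94e-43, and adjusted p = 4.12e-06 with an estimated correlation). The pericentral list, genes of hepatocytes around the central vein, also stood higher, with 2 of 11 genes past the threshold (5 higher and 1 lower adjusted over the list alone; adjusted p = 2.78e-06, and adjusted p = 0.0162 with an estimated correlation). These were Rhbg, an ammonium channel (0.96 ± 0.15, adjusted p = 8.67e-05), and Cyp1a2, which the AhR list holds too. Another 6 lists passed with the preset correlation alone (adjusted p = 0.783 to 0.822 with an estimated correlation). NRF2 genes (2 of 26 higher, 3 adjusted over the list alone) and Kupffer cell markers stood higher, and male-predominant, gluconeogenesis, cell cycle and ribosomal genes lower, with 0 genes of these 5 past the threshold by limma (1 Kupffer cell marker adjusted over the list alone). At an unadjusted p under 0.05 limma called 2008 of all genes. Cyp2c11, the main male-specific oxidase of rat liver, did not pass (-0.45 ± 0.34, adjusted p = 0.797).

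2-ITX at 500 mg/kg/day against control asked which liver genes the ink compound reaches. The clearest change was lower male-type liver expression. All groups were measured after the same 31 days of dosing, so a loss cannot be told apart from expression that never rose. The alpha-2u-globulins, urinary carrier proteins made in the liver of adult male rats, fell more than any other named genes: Mup5 fell by 5.8 ± 0.61 (adjusted p = 5.73e-09, chromosome 5, 78468225 to 78468284) and Obp3 fell by 6.56 ± 0.70 (adjusted p = 7.86e-09). Cyp2c11, which hydroxylates testosterone, fell by 3.81 ± 0.34 (14-fold, lower in 6 of 6 rats, adjusted p = 1.85e-10, chromosome 1, 243320626 to 243320685), and Car3, a carbonic anhydrase of male liver, fell by 3.51 (adjusted p = 4.44e-10). Genes of female rat liver moved the other way. Cyp2c12, the female-specific steroid sulfate hydroxylase, rose by 2.46 ± 0.50 (adjusted p = 0.000553), the prolactin receptor Prlr by 1.74 ± 0.23 (adjusted p = 5.87e-07) and the hydroxysteroid sulfotransferase Sult2a6 by 2.68 ± 0.31 (adjusted p = 3.4e-08), each higher in 6 of 6 rats.

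Of 19 measured male-predominant genes, 11 fell and none rose (13 and 0 adjusted over the list alone; median -1.26; camera adjusted p = 9.21e-19, and adjusted p = 0.00895 with an estimated correlation). Of 12 female-predominant genes, 8 rose and 1, Cyp3a9, fell (9 and 1 adjusted over the list alone; adjusted p = 5.99e-08, but adjusted p = 0.0784 with an estimated correlation). In both sets of sample numbers Cyp2c11 was lower. It fell by 3.97 ± 0.54 from the controls of the same numbers in rats 1 to 3 (adjusted p = 5.87e-06) and by 3.53 ± 0.54 in rats 4 to 6 (adjusted p = 0.000181). Of the male-predominant genes 11 and 7 fell (adjusted p = 0.0129 and 0.0743 with an estimated correlation). Cyp2c12 rose by 3.58 ± 0.70 in rats 1 to 3 (adjusted p = 0.00101) and did not pass in rats 4 to 6 (1.43 ± 0.70, adjusted p = 0.369). Between these sets it did not differ past the threshold (1.77 ± 0.70, adjusted p = 0.18). Growth hormone regulates these genes, and of 13 genes of its axis 5 fell and 1 rose (6 and 2 adjusted over the list alone; adjusted p = 0.00271, but adjusted p = 0.286 with an estimated correlation). Igf1, the growth factor itself, fell by 0.69 ± 0.17 (adjusted p = 0.00417) and its carrier subunit Igfals fell by 0.91 ± 0.22 (adjusted p = 0.0039), while Igfbp1, a binding protein raised in fasting, rose by 1.08 ± 0.33 (adjusted p = 0.0256, not passed in 5 of 19 alternatives). The growth hormone receptor Ghr did not pass (-0.10 ± 0.13, adjusted p = 0.705). The alpha-2u-globulin genes are near-identical copies, so a probe cannot assign its signal to 1 of them.

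**Figure D1:**
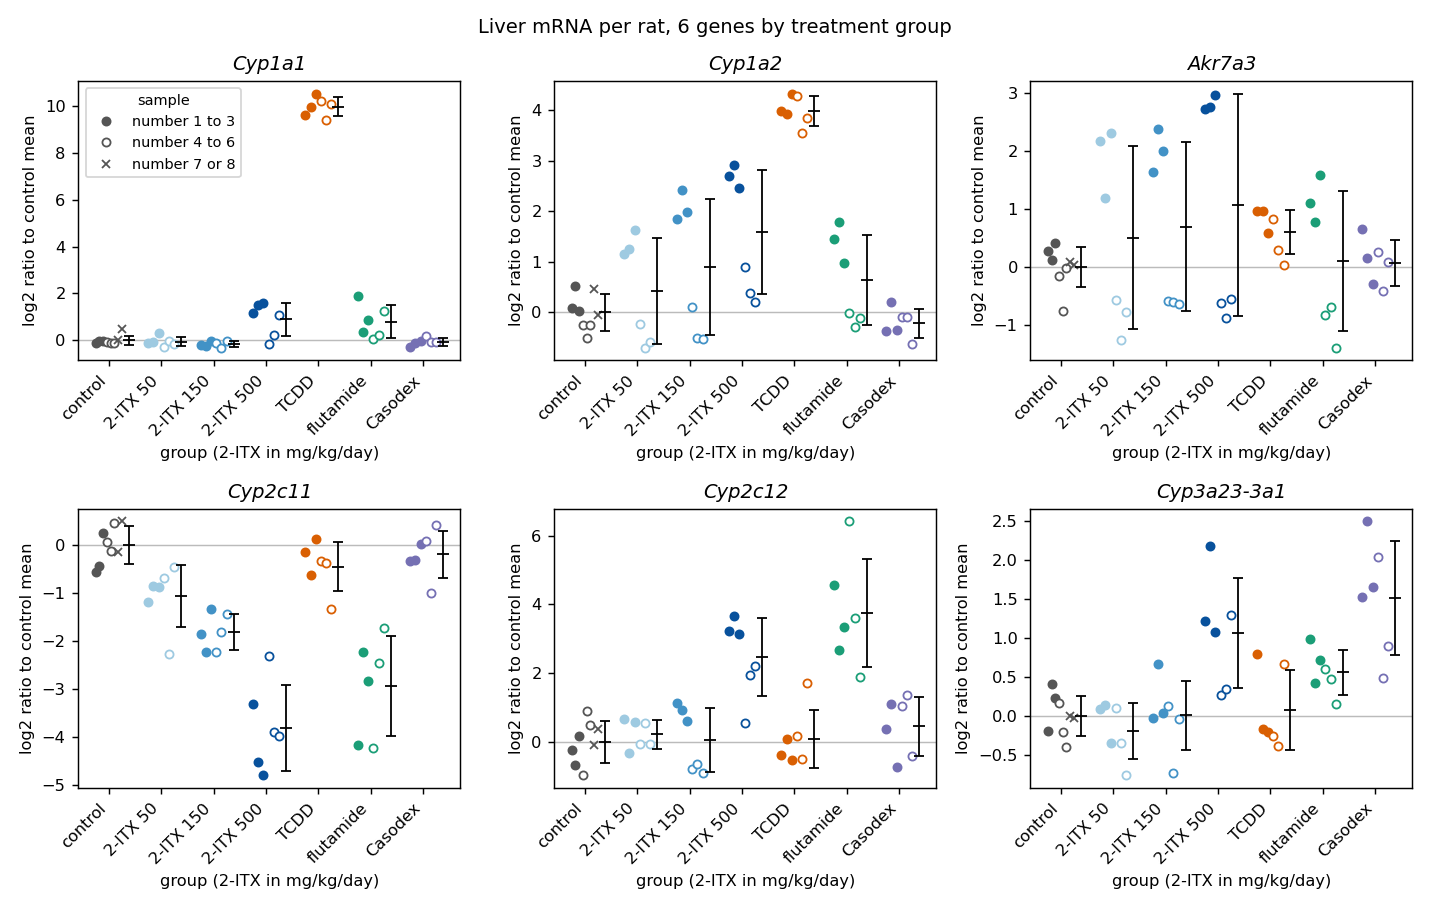
Each panel plots 1 gene, with the log2 ratio to the control mean on the vertical axis and the 7 groups on the horizontal axis. Points are rats, filled for sample numbers 1 to 3, open for 4 to 6 and crossed for 7 and 8; bars are the group mean and SD. Cyp1a2 and Akr7a3, an aldehyde reductase chosen after its values were seen, separate the numbers with 2-ITX and flutamide, and Cyp2c11 does not. In the controls both also separate numbers 1 to 3 from 4 to 6, over a smaller distance. There Cyp1a2 was at 0.03 to 0.52 against -0.51 to -0.25, and Akr7a3 at 0.13 to 0.41 against -0.76 to -0.02.

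At 500 mg/kg/day 2-ITX also raised genes of detoxification. The aldose reductase relatives Akr1b7 and Akr1b8, which reduce reactive aldehydes, rose by 4.85 ± 0.53 (28.9-fold, adjusted p = 1.41e-08, chromosome 4, 61806769 to 61806828) and 4.06 ± 0.47 (16.7-fold, adjusted p = 3.66e-08). Gstp1, a glutathione transferase that the adult rat liver hardly expresses, rose by 4.79 ± 0.57 (27.6-fold, adjusted p = 8.37e-08, chromosome 1, 206627402 to 206627461). Ggt1, which recycles glutathione, rose by 2.65 ± 0.18 (adjusted p = 5.21e-14), and Hmox1, which degrades heme under oxidative stress, by 1.83 ± 0.27 (adjusted p = 5.13e-06). All were higher in 6 of 6 rats. Of the AhR targets, Cyp1a1 rose by 0.90 ± 0.22 (higher in 5 of 6 rats, adjusted p = 0.00381), far less than with TCDD, Cyp1a2 by 1.59 ± 0.45 (adjusted p = 0.0138) and Aldh3a1 by 2.64 ± 0.66 (adjusted p = 0.00521). The Cyp1a1 call was lost in 5 of 18 alternatives, such as quantile normalisation (0.53, adjusted p = 0.0549). Cyp1b1 was above background in 1 of 6 rats and did not pass (adjusted p = 0.857), nor did Nqo1 (0.78 ± 0.44, adjusted p = 0.281) or Tiparp (adjusted p = 0.672).

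Of 26 NRF2 and glutathione genes, targets of the sensor of oxidative stress, 10 rose and none fell (13 and 0 adjusted over the list alone; adjusted p = 2.81e-09, but adjusted p = 0.286 with an estimated correlation). Of 11 AhR genes, 7 rose and none fell (7 and 0 adjusted over the list alone; adjusted p = 2.97e-05, but adjusted p = 0.248 with an estimated correlation). Much of this lay in rats numbered 1 to 3. Their Aldh3a1 values were between 3.82 and 5.92, against 0.07 to 0.29 in rats 4 to 6, and their Cyp1a2 values between 2.46 and 2.91, against 0.20 to 0.90. From controls of the same numbers, Aldh3a1 in rats 1 to 3 rose by 5.01 ± 0.42 (adjusted p = 2.85e-10), and with TCDD by 3.81 ± 0.42 (adjusted p = 3.4e-07). Ugt1a6, a glucuronosyltransferase, rose by 1.67 and 1.70. Against controls of the same numbers, 21 of 26 NRF2 genes and 8 of 11 AhR genes rose in rats 1 to 3 (adjusted p = 0.00188 and 0.00118 with an estimated correlation). In rats 4 to 6, 4 and 2 of them rose (adjusted p = 0.575 and 0.422 with an estimated correlation).

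Other foreign-compound genes changed at 500 mg/kg/day too. Of 24 targets of the drug-sensing receptors CAR and PXR, 13 rose and 2 fell (14 and 2 adjusted over the list alone; adjusted p = 1.3e-06, but adjusted p = 0.153 with an estimated correlation). The carboxylesterase Ces2c rose by 1.27 ± 0.12 (adjusted p = 1.05e-09) and Cyp3a23-3a1, the drug oxidase that PXR controls, by 1.06 ± 0.26 (adjusted p = 0.00347), while Cyp2b1, the usual CAR target, rose by 0.56 ± 0.10 (adjusted p = 7.87e-05, not passed in 3 of 19 alternatives) on the probe used and its other probes did not follow. The carrier Slco1a4 fell by 1.39 ± 0.18 (adjusted p = 3.78e-07). Of 25 cholesterol synthesis genes, 7 rose (11 adjusted over the list alone; adjusted p = 1.64e-05, but adjusted p = 0.457 with an estimated correlation), among them Hmgcr, the controlling step (1.35 ± 0.35, higher in 5 of 6 rats, adjusted p = 0.00687). Of 20 genes of fatty acid synthesis, 7 rose and 2 fell (8 and 3 adjusted over the list alone; adjusted p = 0.0274, but adjusted p = 0.457 with an estimated correlation). The desaturase Fads2 rose by 1.35 ± 0.19 (adjusted p = 1.81e-06), and Fasn, the synthase, did not pass (adjusted p = 0.691).

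At the same dose 5 of 13 p53 targets rose, such as Mdm2, which degrades p53 (0.50 ± 0.09, adjusted p = 0.000124; 6 higher and 1 lower adjusted over the list alone; list adjusted p = 0.0274, but adjusted p = 0.404 with an estimated correlation). Of 15 genes of heme and iron, 5 rose (5 adjusted over the list alone; adjusted p = 0.00839, but adjusted p = 0.457 with an estimated correlation), led by the iron exporter Slc40a1 (0.86 ± 0.10, adjusted p = 3.99e-08). This list stood higher in rats 1 to 3 than in rats 4 to 6 (7 genes higher; adjusted p = 0.0313 with an estimated correlation). Among 24 acute phase genes, 3 fell and 1 rose (6 and 1 adjusted over the list alone; adjusted p = 0.00107, but adjusted p = 0.457 with an estimated correlation), among them the protease inhibitor A2m, which fell by 2.28 ± 0.36 (adjusted p = 1.26e-05). Of 18 genes of the unfolded protein response, 5 fell (8 adjusted over the list alone; adjusted p = 0.00412, but adjusted p = 0.404 with an estimated correlation). Of 13 pancreatic acinar markers, 5 fell (5 adjusted over the list alone; adjusted p = 0.000168, but adjusted p = 0.109 with an estimated correlation). Of 76 ribosomal protein genes, 2 fell (1 adjusted over the list alone; adjusted p = 0.00119, but adjusted p = 0.66 with an estimated correlation).

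Altogether 2788 genes passed at 500 mg/kg/day, 1956 higher and 832 lower, and 567 of them changed at least 1.5-fold. After quantile normalisation 1049 genes passed, and most were still higher (672 higher and 377 lower). The excess of higher calls was nearly gone with the matched scanner files, at 1024 higher and 931 lower with loess and 1721 and 1630 with Agilent's log ratios. In simulated data with 6 against 8 rats, 83.6% of 1.5-fold changes and 97% of 2-fold changes were found for this comparison. Lists that did not pass were PPARA targets (4 of 36 higher and 1 lower, 5 and 2 adjusted over the list alone, adjusted p = 0.486), bile acid genes (2 of 21 higher and 3 lower, 2 and 5 adjusted over the list alone, adjusted p = 0.136), gluconeogenesis (2 of 20 each way by both adjustments, adjusted p = 0.49) and cell cycle (1 of 26 each way, 0 adjusted over the list alone, adjusted p = 0.485). Nor did the circadian clock (1 of 15 higher, Bhlhe41, by 1.33 ± 0.37, adjusted p = 0.0124; 2 adjusted over the list alone, adjusted p = 0.347) and thyroid hormone genes (1 of 8 higher and 3 lower by both adjustments, adjusted p = 0.238), whose test and median were negative and whose mean was 0.05. Clock genes differed between the sample numbers in all groups together, such as Dbp in number 3 (higher by 2.42 ± 0.56, adjusted p = 0.0201), which widens the spread within groups. Dbp at this dose was above the control mean in 5 of 6 rats without passing (2.19 ± 0.88, adjusted p = 0.101), and the list test does not exclude a change of clock genes. With a block for sample number in the limma fit, Dbp passed (1.90, adjusted p = 0.00469). So did Bmal1 (-1.21, adjusted p = 0.0139), Per3 and Tef, while others such as Per2 and Cry1 did not. The pericentral (2 of 11 higher and 1 lower, 2 and 2 adjusted over the list alone, adjusted p = 0.259) and periportal lists (3 of 12 higher and 1 lower, 5 and 1 adjusted over the list alone, adjusted p = 0.176) did not pass either. Among markers of other cell types, with the same counts adjusted over the list alone, neither Kupffer cells and leukocytes (1 of 21 lower, adjusted p = 0.162), stellate cells (0 of 13, adjusted p = 0.176), cholangiocytes (2 of 8 higher, adjusted p = 0.051), endothelium (1 of 11 lower, adjusted p = 0.448) nor blood (1 of 10 lower, adjusted p = 0.486) passed. The tests for the last 2 pointed down and their medians were 0.02 and 0.01. The self-contained test fry, which does not set a list against other genes, did call the clock and periportal lists (adjusted p = 0.0473 for both) and the cholangiocyte list (adjusted p = 0.00622). Over all genes limma called 5703 at an unadjusted p under 0.05.

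**Figure D2:**
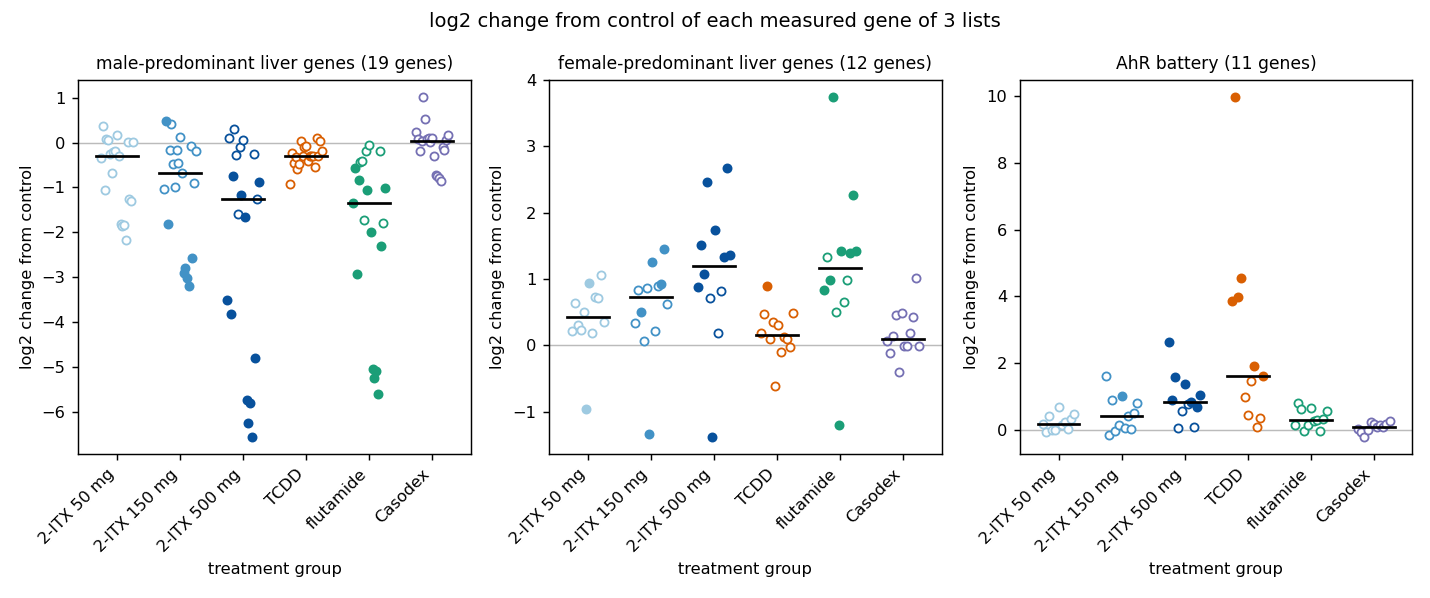
Each panel plots the measured genes of 1 list, with the log2 change from control on the vertical axis and the 6 treated groups on the horizontal axis. Filled points passed the threshold and bars are medians; the male-predominant median was -1.26 with 2-ITX at 500 mg/kg/day and -1.34 with flutamide.

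The lower doses of 2-ITX asked how far down these changes reach. At 150 mg/kg/day Akr1b7 rose by 3.22 ± 0.53 (adjusted p = 0.000197), Akr1b8 by 2.58 ± 0.47 (adjusted p = 0.000544) and Gstp1 by 2.37 ± 0.57 (adjusted p = 0.0111). Cyp2c11 fell by 1.82 ± 0.34 (adjusted p = 0.000743) and Mup5 fell by 3.02 ± 0.61 (adjusted p = 0.002), each in 6 of 6 rats. The female-specific Cyp2c12 did not follow over all 6 rats (mean 0.06, SD 0.93). It was at 0.62 to 1.14 in rats 1 to 3 and at -0.91 to -0.64 in rats 4 to 6. Of the 719 genes that passed, 464 were higher and 255 lower. That split became 309 higher and 407 lower with the matched scanner files and loess, and 435 genes passed without rat 2 of this group. In the male-predominant list 6 of 19 fell and 1 rose (8 and 1 adjusted over the list alone; adjusted p = 4.03e-07, but adjusted p = 0.284 with an estimated correlation). Of 12 female-predominant genes, 4 rose and 1 fell (6 and 1 adjusted over the list alone; adjusted p = 5.07e-05, but adjusted p = 0.284 with an estimated correlation). Another 10 lists passed with the preset correlation, and none of the 12 with an estimated one (adjusted p = 0.284 to 0.476). NRF2 genes (3 of 26 higher; 6 adjusted over the list alone), CAR and PXR targets (3 of 24 higher and 2 lower; 9 and 2 adjusted over the list alone), AhR genes (1 of 11 higher; 1 adjusted over the list alone) and periportal genes (1 of 12 higher; 3 adjusted over the list alone) stood higher. The acute phase and pericentral lists (3 genes lower in each; 4 lower and 1 higher adjusted over the list alone), the unfolded protein list (2 lower; 3 adjusted over the list alone) and the stellate cell, pancreatic and growth hormone lists (1 lower in each; 2, 4 and 5 adjusted over the list alone, with 2 higher in the last) stood lower. Cyp1a1 did not pass (-0.16 ± 0.22, adjusted p = 0.834). Cyp1a2 did not pass over all 6 rats either (0.89 ± 0.45, adjusted p = 0.369). It was higher by 1.87 ± 0.23 in rats 1 to 3 than in controls of the same numbers (adjusted p = 4.55e-06), and by 0.03 ± 0.23 in rats 4 to 6.

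At 50 mg/kg/day few genes passed over all 6 rats. Esm1, a secreted proteoglycan, rose by 1.22 ± 0.24 (adjusted p = 0.0123), and Prlr by 0.94 ± 0.23 (adjusted p = 0.0457). The peptidase Mme fell by 1.05 ± 0.21 (adjusted p = 0.0123). All 3 moved so in 6 of 6 rats, and their calls were lost in 4, 10 and 5 of 18 or 19 alternatives. Of the 118 genes that passed, 96 were higher and 22 lower. With the matched scanner files the split was 5 higher and 3 lower with loess and 80 and 38 with Agilent's log ratios. The count rests on single rats: 68, 66, 57 and 48 genes passed without control 1, 5, 7 or 8, and 42, 44, 32 and 62 without rat 1, 3, 5 or 6 of this group. Cyp2c11 was lower in 6 of 6 rats without passing (-1.06 ± 0.34, adjusted p = 0.215). For Cyp2c12 the mean of the 6 rats was 0.23 (SD 0.42). None of 19 male-predominant genes passed over all genes by limma (1 higher and 7 lower adjusted over the list alone), while the list stood lower (adjusted p = 3.35e-05, but adjusted p = 0.398 with an estimated correlation). Another 8 lists passed with the preset correlation, and none of the 9 with an estimated one (adjusted p = 0.398 to 0.697). The female-predominant, NRF2, cholesterol and ribosomal lists stood higher, and the cell cycle, pericentral, stellate cell and pancreatic lists lower over all 6 rats. In these, 1 female-predominant gene rose and 1 fell (5 and 1 adjusted over the list alone), and no gene of the other 7 passed over all genes (1 NRF2 gene higher and 3 pericentral genes lower adjusted over the list alone). At this dose 2069 genes had an unadjusted p under 0.05.

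In rats 1 to 3 the AhR and NRF2 genes stood higher at both lower doses than in controls of the same numbers. The division, and Akr7a3, were picked from these values, so the p-values here are descriptive and no independent evidence of an effect. Over all 6 rats at 50 mg/kg/day, neither list passed camera with an estimated correlation (adjusted p = 0.697 for both). At 150 mg/kg/day 6 of 11 AhR genes and 8 of 26 NRF2 genes rose (adjusted p = 0.00766 and 0.00847 with an estimated correlation). In rats 4 to 6 none did by limma (adjusted p = 0.858 and 0.871 with an estimated correlation). At 50 mg/kg/day 1 gene of each list rose in rats 1 to 3 (adjusted p = 0.0439 for both with an estimated correlation), and none in rats 4 to 6 (adjusted p = 0.969 for both). Ugt1a6 was higher by 0.96 ± 0.18 in rats 1 to 3 at this dose (adjusted p = 0.034), and Akr7a3 by 1.62 ± 0.27 (adjusted p = 0.0108). Several lists at 50 mg/kg/day had medians of opposite sign in the 2 sets, and 3 that passed over all 6 rats are given here. The cell cycle list stood higher in rats 1 to 3 (median 0.24; adjusted p = 3.15e-05, but adjusted p = 0.373 with an estimated correlation) and lower in rats 4 to 6 (median -0.28; adjusted p = 8.78e-12, but adjusted p = 0.898 with an estimated correlation). The sets differed directly in this list (1 gene higher in rats 1 to 3; adjusted p = 0.0116 with an estimated correlation). The medians of the cholesterol list were -0.08 in rats 1 to 3 and 0.55 in rats 4 to 6 (adjusted p = 1.22e-05 in the latter, but adjusted p = 0.969 with an estimated correlation), without a difference between the sets (adjusted p = 0.983). Those of the stellate cell list were -0.30 and 0.13 (adjusted p = 1.31e-05 in rats 1 to 3, but adjusted p = 0.295 with an estimated correlation), and the sets differed with the preset correlation alone (adjusted p = 0.00391, but adjusted p = 0.418 with an estimated correlation).

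The doses were compared over the genes that passed at 500 mg/kg/day, which share their controls with the lower doses. Of these 2788 genes, 98.6% had the same sign at 150 and 96.8% at 50 mg/kg/day. With unchanged lower doses simulated against the same controls, the medians were 62.7% and 64.8% and the highest of 100 draws 87.9% and 84.1%. With the controls split into 2 sets of 4, 1 for each dose, the medians were 95.1% and 89.5%, and 60.5% for Casodex. Ordered by dose were 72.2%, at the edge of the 26.5% to 72% that held 95% of the simulated draws. Of 924 ways to assign the 12 rats to 50 and 150 mg/kg/day, 26 gave as high an ordered share (exact permutation test, one-sided p = 0.0281). Both 150 and 500 mg/kg/day raised 420 genes, where independent lists would share 38.8, and lowered 223, against 9.07, with a median of 248.5 shared with split controls. For 50 and 500 they were 87, against 8.03, and 22, against 0.782, with a median of 9. These checks were chosen after the values were seen. Between 500 and 50 mg/kg/day directly, 346 genes differed, 207 higher and 139 lower at 500. Quantile normalisation gave 29 higher and 13 lower, and 217, 207 or 199 genes differed without rat 2 at 50 or without rat 2 or 3 at 500 mg/kg/day. Cyp2c11 was lower by -2.75 ± 0.36 at the higher dose (adjusted p = 4.52e-06) and Cyp1a1 higher by 0.96 ± 0.23 (adjusted p = 0.0201, not passed in 7 of 18 alternatives).

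Flutamide, per the design text, blocks the androgen receptor and also activates the AhR. Its comparison with control covered the same liver genes and cannot assign a change to either action. Male-type expression fell as it did with 2-ITX. Mup5 fell by 5.08 ± 0.61 (adjusted p = 1.82e-06) and Cyp2c11 fell by 2.94 ± 0.34 (7.67-fold, adjusted p = 1.09e-06). Female-type genes rose: Cyp2c12 by 3.75 ± 0.50 (13.4-fold, adjusted p = 5.84e-06), Sult2a6 by 2.27 ± 0.31 (adjusted p = 8.19e-06), and Trim24, a nuclear receptor cofactor, by 1.43 ± 0.26 (adjusted p = 0.00109). Akr1b7 rose by 3.54 ± 0.53 (adjusted p = 5.88e-05). Each of these moved so in 6 of 6 rats. Of 19 male-predominant genes, 12 fell and none rose (14 and 0 adjusted over the list alone; adjusted p = 3.33e-44, and adjusted p = 1.23e-05 with an estimated correlation). Of 12 female-predominant genes, 7 rose and 1 fell (10 and 1 adjusted over the list alone; adjusted p = 4.13e-17, and adjusted p = 0.0012 with an estimated correlation).

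Flutamide changed 236 genes, 151 higher and 85 lower. The balance turned to 90 higher and 95 lower after quantile normalisation, and to 38 and 87 with loess or 126 and 166 with Agilent's log ratios on the matched scanner files. Without rat 4 of the group, 139 genes passed. Of its AhR genes, Cyp1a1 was higher in 6 of 6 rats without passing (0.79 ± 0.22, adjusted p = 0.0645, passed in 3 of 18 alternatives) and Cyp1a2 did not pass over all rats (0.63 ± 0.45, adjusted p = 0.638). In rats 1 to 3, Cyp1a2 was higher than in controls of the same numbers by 1.19 ± 0.23 (adjusted p = 0.0183), and by 0.20 ± 0.23 in rats 4 to 6 (adjusted p = 0.802). CAR and PXR targets stood higher (3 of 24 higher and 1 lower; 4 and 1 adjusted over the list alone; adjusted p = 0.0222, but adjusted p = 0.901 with an estimated correlation).

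Casodex against control tested the other blocker of the androgen receptor. Neither Cyp2c11 (-0.19 ± 0.34) nor Cyp2c12 (0.46 ± 0.50) passed (adjusted p = 1 for both). Single rats lay outside the controls, with Cyp2c11 down to -1 (lowest control -0.56) and Cyp2c12 up to 1.36 (highest control 0.91). Its clearest effect was on Cyp3a23-3a1, which rose by 1.51 ± 0.26 (2.86-fold, higher in 6 of 6 rats, adjusted p = 0.0139, chromosome 12, 9567010 to 9567069). The other gene of the 2 that passed, the transcript ENSRNOT00000002705, which has no symbol (chromosome 14, 22099965 to 22100024), rose by 0.99 ± 0.19 (adjusted p = 0.0495, not passed in 12 of 19 alternatives) and was named after its values were seen. The count was 1 without control 1, 2, 3, 4, 5, 7 or 8, 0 without Casodex rat 1, 2, 3 or 4, and 6 without Casodex rat 6. By limma, 685 of 23396 genes had an unadjusted p under 0.05, a smaller share than the 0.05 that chance alone gives. Of 24 CAR and PXR targets 1 rose (6 adjusted over the list alone; adjusted p = 2.46e-10, but adjusted p = 0.0952 with an estimated correlation). Bile acid genes stood higher, and pericentral and Kupffer cell genes lower, with 0 genes past the threshold by limma (3 bile acid genes adjusted over the list alone; adjusted p = 0.0397, 0.0439 and 0.021, but adjusted p = 0.909 with an estimated correlation).

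Flutamide and Casodex were also compared directly. Their doses differed, so the difference is one between these treatments and not between equal doses. With flutamide, Cyp2c12 was higher by 3.29 ± 0.53 (95% interval 2.21 to 4.37, adjusted p = 0.000405) and Cyp2c11 lower by -2.75 ± 0.36 (-3.48 to -2.02, adjusted p = 2.11e-05). Akr1b7 was higher by 3.54 ± 0.57 (adjusted p = 0.000369) and Trim24 by 1.44 ± 0.28 (adjusted p = 0.00373), while the drug oxidase Cyp3a18 was lower by -1.44 ± 0.25 (adjusted p = 0.000911). All 6 flutamide rats lay on that side of the Casodex mean. Of 101 genes that differed, 39 were higher and 62 lower with flutamide, or 26 and 78 with the matched scanner files and loess, and 67 differed without Casodex rat 6. When these 2 groups alone were fitted, 0 genes passed by limma, with 1828 at an unadjusted p under 0.05. Of 19 male-predominant genes, 13 were lower and none higher (16 and 0 adjusted over the list alone; adjusted p = 2.68e-53, and adjusted p = 1.88e-06 with an estimated correlation). Of 12 female-predominant genes, 4 were higher and 1 lower (11 and 1 adjusted over the list alone; adjusted p = 7.92e-18, and adjusted p = 0.0009 with an estimated correlation).

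2-ITX at 500 mg/kg/day was set against TCDD to ask how much of its profile an AhR agonist gives. The profiles differed in AhR strength and in male-type expression. Cyp1a1 was lower with 2-ITX by -9.09 ± 0.23 (adjusted p = 3.54e-29) and Cyp1a2 by -2.39 (adjusted p = 0.000981). Cyp2c11 was lower with 2-ITX by -3.36 ± 0.36 (adjusted p = 2.07e-08), and Akr1b8 was higher by 3.73 ± 0.50 (adjusted p = 1.6e-06), all in 6 of 6 rats. In all 1223 genes differed, 833 higher and 390 lower with 2-ITX. Quantile normalisation gave 228 and 205, and the matched scanner files 555 and 412 with loess and 956 and 727 with Agilent's log ratios. Without rat 3 of the 2-ITX group 770 differed. The male-predominant list stood lower with 2-ITX (9 of 19 lower and 1 higher; 13 and 2 adjusted over the list alone; adjusted p = 5.36e-16, and adjusted p = 0.0109 with an estimated correlation). So did the AhR list (4 of 11 lower and 1 higher; 4 and 1 adjusted over the list alone; adjusted p = 4.95e-11, and adjusted p = 0.0263 with an estimated correlation) and the pericentral list (4 of 11 lower; 7 adjusted over the list alone; adjusted p = 7.59e-07, and adjusted p = 0.0109 with an estimated correlation). Another 15 lists passed with the preset correlation alone (adjusted p = 0.0656 to 0.593 with an estimated correlation).

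Some changes were common to 2-ITX at 500 mg/kg/day and TCDD. Both raised 59 of the same genes, where independent lists would share 11.1, and lowered 15, against 0.605. In opposite directions 2 genes passed. Among those raised by both were Gstp1, Aldh3a1, Cyp1a1, Cyp1a2 and Selenbp1, a selenium-binding AhR target (0.83 ± 0.17 and 1.91 ± 0.17). Across genes, which are not independent replicates, the log2 changes correlated at r = 0.44. Unchanged groups simulated against the same controls gave a median of 0.45. The covariance was 0.02, against 0.005 simulated. With the controls split into 2 sets of 4, a median of 31 genes were shared, r was 0.31 and the covariance 0.0157.

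2-ITX at 500 mg/kg/day and flutamide shared more. The alpha-2u-globulins, Cyp2c11 and Car3 fell with both, and Akr1b7, Cyp2c12, Sult2a6 and Gstp1 rose with both. The lists shared 123 higher genes, against 12.6 for independent lists, and 75 lower ones, against 3.02, with 0 in opposite directions. Across genes r was 0.75, above the 0.62 that bounded 95% of simulated unchanged groups, and the covariance was 0.0403. With split controls, a median of 78.5 genes were shared, r was 0.61 and the covariance 0.0358. Directly, 551 genes differed between them, 341 higher and 210 lower with 2-ITX, and 361 or 322 without rat 1 or 3 of the 2-ITX group. Cyp2c11 did not differ past the threshold (-0.87 ± 0.36, 95% interval -1.60 to -0.14, adjusted p = 0.24), nor did Cyp2c12 (-1.29 ± 0.53, adjusted p = 0.234). Aldh3a1 was higher with 2-ITX by 2.51 ± 0.71 (adjusted p = 0.0454, not passed in 10 of 19 alternatives), in 4 of 6 rats. Cyp2b1 was higher by 0.46 ± 0.10 (adjusted p = 0.00852) on the probe used, and at -0.06, not passed, as the average of its probes.

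With Casodex, 2-ITX at 500 mg/kg/day shared 2 higher genes and no lower one (0.167 for independent lists; r = 0.31, covariance 0.0083), and flutamide shared 1 with Casodex (0.0129; r = 0.40, covariance 0.0074). Both counts were 0 with split controls, by limma at the same threshold. Against all controls, Casodex had 685 genes at an unadjusted p under 0.05, fewer than chance alone gives. TCDD and flutamide shared 9 higher and 6 lower genes, against 0.858 and 0.0618 for independent lists (r = 0.36, covariance 0.0115), and a median of 2 with split controls.

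**Figure D3:**
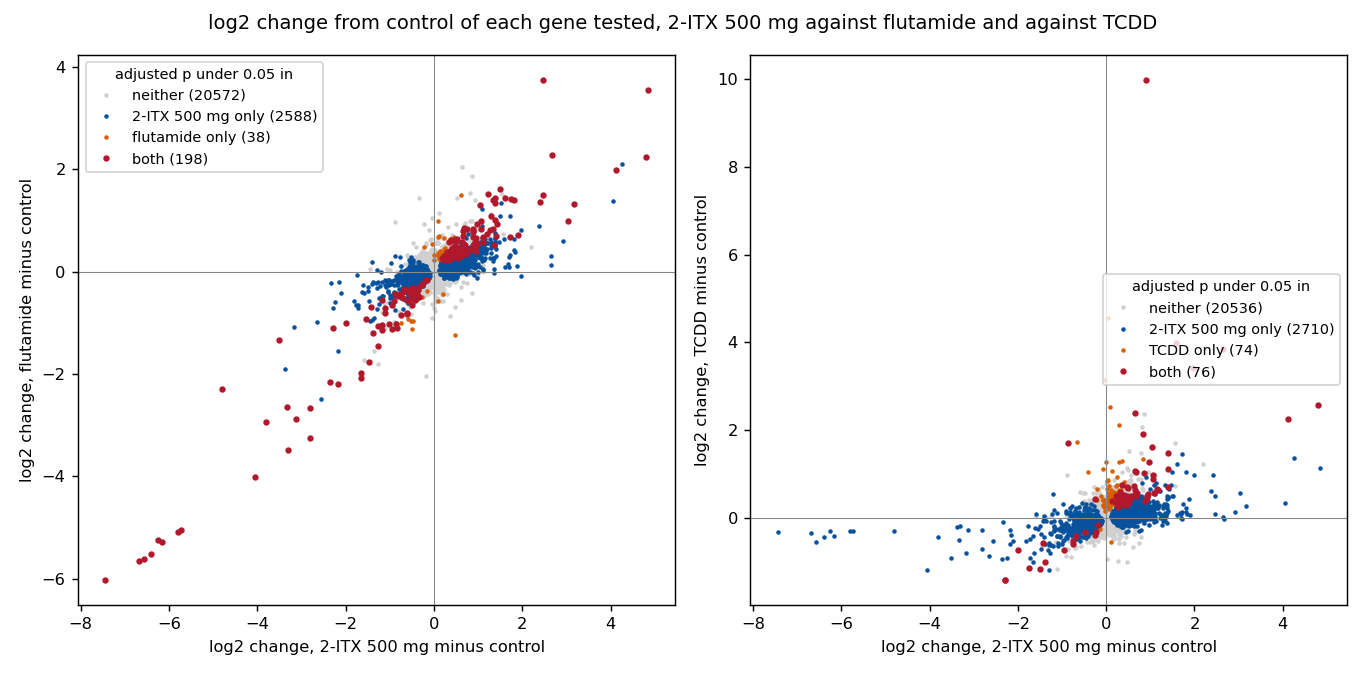
Each point is a gene, with its log2 change from control under 2-ITX at 500 mg/kg/day on the horizontal axis and under flutamide (left) or TCDD (right) on the vertical axis. Colours mark where the gene passed the threshold; 198 genes passed with the same sign beside flutamide and 74 beside TCDD.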

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

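The tests of the recorded files, of AhR strength and of the sample numbers were chosen only after the result was seen; those of the clock and of the alpha-2u-globulin copies in the male-predominant list, and the splits, were set before.

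Each value was compared with the other samples of its group. Of 169 groups of values examined, 10 held a sample far from the others, and chance flags about 1 in 20 groups. For the mean of the male-predominant genes, rat 4 with 2-ITX at 500 mg/kg/day was at -1.5 (the others -2.36 to -2.66), TCDD rat 6 at -0.89 (the others -0.29 to -0.08) and Casodex rat 5 at -1.14 (the others -0.09 to 0.53). The median of all genes was -0.16 in TCDD rat 6 (the others -0.01 to 0.06), and the score on the first principal component was -12.79 in TCDD rat 5 (the others -7.98 to -5.18). Among single genes, Cyp1a1 was at 0.49 in control 8 (the others -0.12 to -0.01), Cyp1b1 at 0.42 in rat 1 of 2-ITX at 500 mg/kg/day (the others at -0.03) and 0.14 in control 5 (the others -0.03 to 0.02), Slc40a1 at -0.27 in control 1 (the others -0.04 to 0.12) and Trim24 at 0.43 in Casodex rat 5 (the others -0.24 to 0.00). Casodex rat 5 thus stood out with lower male-predominant genes and with higher Trim24, a female-predominant gene, and no explanation of it was tested.

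Other splits of the same samples, 100 for each comparison with the real one included, were fitted in the same way. For 6 comparisons the real split gave more changed genes than every other. For 2-ITX at 50 and at 500 against 50 mg/kg/day it did so only with all rats in the fit. A share of 1 in 100, the smallest these splits can give, argues against chance if rats are independent replicates. Structure by sample number puts that in doubt, so chance is not excluded. With the 2 groups fitted alone, 0 genes passed for flutamide against Casodex. With slide added to such a fit, 0 passed for 2-ITX against TCDD too. As many changed genes as the real split were found in 1 of 100 splits for 2-ITX at 50 (118 genes, highest other 65), 150 (719, highest other 1) and 500 mg/kg/day (2788, highest other 1065), for flutamide (236, highest other 33), 2-ITX at 500 against 50 mg/kg/day (346, highest other 274), flutamide against Casodex (101, highest other 33), and 2-ITX at 500 mg/kg/day against TCDD (1223, highest other 521) and against flutamide (551, highest other 264). For TCDD (150) 2 of 100 splits gave as many, the highest other 503, and for Casodex (2 genes) 2 of 100, the highest other 3. The share is small for these 2 as well, but another split gave more genes than the real one, and the Casodex count was 0 without single rats. The count at 50 mg/kg/day dropped to 32 without rat 5, and that for 500 against 50 to 199 without rat 3 at 500, each below the highest other split, and at 50 mg/kg/day the matched files with loess gave 8. The TCDD split with 503 genes, several times the real count, points to a structure of the samples. It set TCDD rats 1 and 6 with controls 1, 2, 4 and 5, which does not follow the sets of numbers below, and its cause was not tested.

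No gene passed by limma with the scanner files as recorded, and many with the value table. The best match of 43 of 44 columns was a file recorded for another sample. Wrong TCDD labels on the columns are argued against by Cyp1a1, over 5 log2 units above the control mean in 6 of 6 columns labelled TCDD and 0 others. A candidate explanation is that files and samples were joined in another order at deposit. Labels within the other groups stay open, since no gene of that kind marks them.

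Male-predominant genes were lower with 2-ITX at 500 mg/kg/day (median -1.26). A shift in clock phase is argued against by a fit with the clock genes Dbp minus Bmal1 as a covariate, which left the median at -1.28. Near-identical alpha-2u-globulin copies counted as many genes are argued against by the list without them, with a median of -0.87 over 15 genes. AhR activation of the strength TCDD gave is argued against by the direct difference from TCDD, with a median of -1.24. Flutamide lowered this list as well (median -1.34). With Casodex, the other blocker of the androgen receptor, its median was 0.04 and 0 of 19 genes passed by limma. Adjusted over the list alone 1 gene was higher, and camera with an estimated correlation gave adjusted p = 0.909. Of all genes 685 had an unadjusted p under 0.05 with Casodex, fewer than chance alone gives. A loss of androgen or growth hormone signalling could lie behind the 2-ITX change as a hypothesis, for which the 2 blockers point different ways and which no test here decides; food intake and body weight are not in the labels and stay open.

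NRF2 and glutathione genes were higher in sample numbers 1 to 3 than in 4 to 6 with 2-ITX and flutamide (median difference 0.76). An exact permutation of the numbers within the 4 groups gave 2 of 160000 orders as large (p = 1.25e-05, the smallest it can give). It takes the rats of a group as exchangeable, which cage mates need not be. The division, the 4 groups and the list were chosen from these values, so this p does not exclude chance. Clock phase as the whole cause in this list is argued against by a median of 0.78 with the clock covariate (22 members). Slide as the whole cause is argued against more weakly, by a median of 0.83 with slide in the fit (14 of 26 members past the threshold, against 22 without). Only 5 of the 11 slides held both sets among these 4 groups, so slide and set are partly confounded. A batch acting on every group alike is argued against by 0.11 in the control, TCDD and Casodex groups. A batch that acts less on the controls is not, since Gsr split them the same way (0.06 to 0.19 against -0.20 to -0.05). Over all genes, 2973 differed between the sets in a fit of these 4 groups alone (3017 in the fit of all samples) and 496 with slide in it, so a part of slide in the other genes stays open. Numbers 1 to 3 may have shared a cage, or the time between last dose and collection may have differed between the sets. Neither is in the labels, so both stay open. If a set shared a cage, its rats would not be independent replicates in the comparisons of groups.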

How the results depend on the processing

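The alternatives with matched scanner files, column centring, quantile normalisation, slides, the clock covariate and the block of number sets were chosen after seeing the data, and the others before. Counts below are genes past the threshold by limma, with the reported count in brackets. Except where a cause is given, the cause was not tested.

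With the scanner files as recorded, 0 genes passed in each of the 10 comparisons with loess or with Agilent's log ratios. At an unadjusted p under 0.05 there were 504 to 1862 and 833 to 1281. Shared changes and AhR control genes were 0 as well (5). The lists that passed with loess were 5 (14) for 2-ITX at 500 mg/kg/day, 5 (12) at 150, 4 (9) at 50, 5 (8) for TCDD, 2 (4) for Casodex, 10 (2) for flutamide against Casodex and 5 (18) for 2-ITX against TCDD. With Agilent's log ratios they were 4 for 2-ITX at 500, 7 at 150, 5 for TCDD, 7 for flutamide against Casodex and 8 for 2-ITX against TCDD. These files were recorded under other samples, which the profile match shows.

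With the matched scanner files and loess, 8 genes (118) passed for 2-ITX at 50 mg/kg/day, 72 (150) for TCDD, 125 (236) for flutamide and 1 (2) for Casodex. Shared changes were 34 (74) for 2-ITX at 500 mg/kg/day and TCDD, 104 (198) with flutamide, 1 (2) with Casodex, 0 (1) for flutamide and Casodex and 2 (15) for TCDD and flutamide, and 2 lists (4) passed for Casodex. Aquantile after loess gave the same values, since it leaves ratios as they are. Without background subtraction 71 genes passed for 2-ITX at 50 and 1193 (719) at 150 mg/kg/day, 1 for Casodex, 603 (346) for 500 against 50 and 1050 (551) for 2-ITX against flutamide. Agilent's log ratios gave 1287 at 150 mg/kg/day, 1 for Casodex, 603 for 500 against 50, 1075 for 2-ITX against flutamide and 1 list for Casodex. In both, 1 change was shared by 2-ITX and Casodex and 0 by flutamide and Casodex. With median centring in place of loess 0, 46 and 190 genes passed for 2-ITX at 50, 150 and 500 mg/kg/day, 12 for TCDD, 29 for flutamide, 0 for Casodex, 30 for 500 against 50, 22 (101) for flutamide against Casodex, and 82 (1223) and 20 for 2-ITX against TCDD and flutamide (587 and 419 at an unadjusted p under 0.05 where the count was 0). Shared changes were 1 with TCDD, 25 with flutamide and 0 for the other 3 pairs, and 3 AhR control genes passed.

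Quantile normalisation of the columns gave 1049 (2788) genes for 2-ITX at 500 mg/kg/day, 4 for Casodex, 42 for 500 against 50, 433 for 2-ITX against TCDD and 62 against flutamide, 1 change shared by 2-ITX and Casodex, 0 by flutamide and Casodex, and 5 lists (3) for flutamide. Centring the columns on their median, all probes, the average of probes and the clock covariate moved no count by over 1.5 times. Without the filter on dim probes 77 genes passed for 2-ITX at 50 mg/kg/day and 1 for Casodex, with 1 and 0 changes shared with Casodex and 6 lists for flutamide. With probes above background in both channels on all arrays, 3 AhR control genes were left to pass, since fewer were tested.

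With the 2 groups compared alone, and so fewer samples for the variance, 0 genes passed for Casodex (906 at an unadjusted p under 0.05), 113 for 500 against 50, 0 for flutamide against Casodex (1828), 610 for 2-ITX against TCDD and 80 against flutamide. The labels do not say what the sample numbers share. Samples of 1 number correlated at a mean r of 0.15 across groups (-0.03 for other numbers), 29 of 42 correlated best with their own number, and in no comparison were all 6 pairs over 0.1. The data thus show a factor shared by sample number, which the labels do not name and which the main fit leaves out. With Dbp minus Bmal1 as a covariate the mean r for the same number fell to 0.08 (-0.01 for other numbers). A part of the factor thus follows these clock genes. The replicate block gave 75 genes for 2-ITX at 50 mg/kg/day, 366 for flutamide, 1 for Casodex, 576 for 500 against 50 and 923 for 2-ITX against flutamide; 1, 0 and 39 shared changes for 2-ITX and Casodex, flutamide and Casodex, and TCDD and flutamide; and 5 lists for flutamide and 2 for Casodex. With it the clock genes Dbp (1.90, adjusted p = 0.00469), Bmal1 (-1.21, adjusted p = 0.0139), Per3 (0.40, adjusted p = 0.00256) and Tef (0.45, adjusted p = 0.0453) passed for 2-ITX at 500 mg/kg/day, which they did not without (adjusted p = 0.101, 0.143, 0.0534 and 0.256). Dbp was above the control of the same number in 6 of 6 rats. A block for numbers 1 to 3, 4 to 6 and 7 to 8 gave 46 genes for 2-ITX at 50 mg/kg/day and 1 for Casodex, 1, 0 and 26 shared changes for the same pairs, and 5 and 2 lists. With slide as a fixed block the counts were 55 for 2-ITX at 50 mg/kg/day, 1 for Casodex, 181 for 500 against 50 and 698 for 2-ITX against TCDD, with 1, 0 and 6 shared changes for those pairs. As a random block (consensus correlation -0.003) it gave 1 for Casodex and 1 and 0 shared changes with it. Over the 2 groups alone with slide, 0 genes passed for flutamide against Casodex and for 2-ITX against TCDD (1014 and 1460 at an unadjusted p under 0.05), with few degrees of freedom left. Array weights (0.23 to 1.72) gave 319 genes for TCDD, 359 for flutamide, 4 for Casodex and 195 for flutamide against Casodex, and 136 and 29 shared changes of TCDD with 2-ITX and flutamide. A trended, robust variance gave 20 genes for 2-ITX at 50 mg/kg/day, 1 for Casodex, and 1, 0 and 4 shared changes for 2-ITX and Casodex, flutamide and Casodex, and TCDD and flutamide.

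A threshold of 1.5-fold on top left 21, 172 and 567 genes for 2-ITX at 50, 150 and 500 mg/kg/day, 59 for TCDD, 98 for flutamide, 156 for 500 against 50, 363 for 2-ITX against TCDD and 184 against flutamide, and 31, 80 and 8 shared changes of 2-ITX with TCDD, 2-ITX with flutamide and TCDD with flutamide. Of lists, camera with an estimated correlation passed 1 for 2-ITX at 500, 0 at 150 and 0 at 50 mg/kg/day, 2 for TCDD, 0 for Casodex and 3 for 2-ITX against TCDD. The self-contained test fry passed 14 (14) for 2-ITX at 500 mg/kg/day, with the clock, periportal and cholangiocyte lists in place of the acute phase, unfolded protein and ribosomal lists (adjusted p = 0.137, 0.0611 and 0.566). It passed 3 at 150 and 0 at 50 mg/kg/day, 2 for TCDD, 0 for Casodex and 9 for 2-ITX against TCDD. With the controls split, shared changes were 31 with TCDD and 78.5 with flutamide, 0 with Casodex for both others, and 2 for TCDD and flutamide.

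With each array left out in turn, counts ran from 32 to 110 for 2-ITX at 50 mg/kg/day, 435 to 750 at 150, 1956 to 2959 at 500, 101 to 200 for TCDD, 139 to 295 for flutamide, 0 to 6 for Casodex, 199 to 415 for 500 against 50, 67 to 115 for flutamide against Casodex, and 770 to 1284 and 322 to 684 for 2-ITX against TCDD and flutamide. The counts moved by over 1.5 times without these arrays. At 50 mg/kg/day they were 68, 66, 57 and 48 without control 1, 5, 7 or 8, and 42, 44, 32 and 62 without treated rat 1, 3, 5 or 6. At 150 mg/kg/day 435 were left without rat 2, and for flutamide 139 without rat 4. For Casodex there was 1 without control 1, 2, 3, 4, 5, 7 or 8, 0 without treated rat 1, 2, 3 or 4, and 6 without rat 6. For 500 against 50 they were 217 without rat 2 at 50, and 207 and 199 without rats 2 and 3 at 500. They were 770 for 2-ITX against TCDD without rat 3, 361 and 322 against flutamide without rats 1 and 3, and 67 for flutamide against Casodex without Casodex rat 6.

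Of 82 changes of single genes, 40 kept their direction and side of the threshold in every alternative run. Over 1548 results of single genes under alternatives, 1434 kept both, 99 kept the direction and fell short of the threshold, 7 kept it and passed, and 8 changed sign. Those 8 are near 0 and not past the threshold: Tiparp with 2-ITX at 500 mg/kg/day at 0 with matched files and loess or Aquantile and -0.07 with median centring, where Tiparp with TCDD was at -0.13, Cyp2c11 with Casodex at 0.1 and Fasn at -0.07; Cyp1b1 with 2-ITX at -0.03 without background subtraction; and Cyp2b1 in 2-ITX against flutamide at -0.06 as the average of its probes, the one of them that had passed.

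Not run were single-slide fits of the 2 pairs, since a slide holds 1 array of a group, mean signals, which 43 files lack, and the single genes in the files as recorded. Other settings of background and normalisation were run on the matched files in place of the files as recorded. Signal over background limits Cyp1b1, which no control showed.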

Other observations

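All tests in this part were chosen after the values were seen, and Akr7a3 and Gsr were picked from their values.

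Sample numbers 1 to 3 and 4 to 6 differed in 33 genes with 2-ITX at 50 mg/kg/day, 333 at 150, 649 at 500 and 58 with flutamide, and in 1 with TCDD. By limma 0 genes differed in the controls and with Casodex, where 1101 and 1004 had an unadjusted p under 0.05. Both are a smaller share of the genes tested than the 0.05 that chance alone gives. Of the 10 ways to divide 6 numbers into 2 sets of 3, applied alike to the 2-ITX and flutamide groups, this one gave 2973 genes and the next highest 36. These fits held these groups alone, with 1 term for the set, while the 3017 and 264 genes of the report came from the fit of all 44 samples with 1 mean per group and set. In the control, TCDD and Casodex groups it gave 127, while numbers 1, 2 and 4 against the rest gave 551.

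Over the 2-ITX and flutamide groups, Akr7a3, which reduces reactive aldehydes, was higher by 2.75 ± 0.13 in numbers 1 to 3 (adjusted p = 1.17e-15), and Cyp1a2 by 1.99 ± 0.11 (adjusted p = 6.56e-14). In the other 3 groups Akr7a3 was higher by 0.41 and Cyp1a2 by 0.28 (adjusted p = 0.447), and the difference between the 2 sets of groups was 2.34 (adjusted p = 1.87e-08) and 1.71 (adjusted p = 3.87e-07). Gsr, which regenerates glutathione, differed likewise (0.99 against 0.23; adjusted p = 1.29e-05 for the difference). Cyp2c11 did not pass (-0.22 ± 0.27, adjusted p = 0.66). Of 26 NRF2 genes 22 were higher (adjusted p = 0.000911 with an estimated correlation), and of 24 acute phase genes 13 were lower (adjusted p = 0.021 with an estimated correlation).

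Each sample number was also compared with the rest over all groups, 7 samples each. Number 6 differed in 1867 genes, of which 234 were higher and 1633 lower. Its samples include TCDD rat 6, whose median over all genes was -0.16, and no such fit without that rat was run. Number 3 differed in 212 genes, number 4 in 106, number 1 in 104 and number 5 in 1. Number 2 differed in 0 by limma, with 2197 at an unadjusted p under 0.05. The clock genes Dbp and Bmal1 were among the genes that differed. Dbp was higher in number 3 by 2.42 ± 0.56 (adjusted p = 0.0201) and in number 6 by 2.08 (adjusted p = 0.0236). Other genes differed in number 3 at far smaller adjusted p. Dlk1 was higher by 1.16 ± 0.06 (adjusted p = 3.14e-18) and Rbm38 by 1.54 ± 0.10 (adjusted p = 3.23e-14). The clock genes are thus not the strongest difference of number 3, and its cause was not tested.

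The probe that read Atad1, a mitochondrial ATPase, at 4.12 with 2-ITX at 500 mg/kg/day was not followed by the second Atad1 probe (0.03), so the gene was not reported as changed.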
